A study of Saccharomyces cerevisiae with 30 samples.

How the data were processed

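The series holds 28 calling card libraries, 1 per transcription factor, and 2 polyA RNA-seq libraries of Saccharomyces cerevisiae, 1 from rich medium and 1 from nitrogen-starved medium. Per the series' design text the yeast was Σ1278b, a strain that grows as filaments when nitrogen is scarce. In the calling card method a factor is fused to Sir4, which draws the Ty5 retrotransposon to the DNA where the factor sits, so that the insertions mark its binding sites. Per the labels' protocols, cells of a low-ammonium synthetic medium were induced in 2% galactose, DNA of colonies with an insertion was cut in 3 separate digests, circularised and amplified outward from Ty5 for Illumina sequencing. The 2 RNA libraries carry the same calling card protocol text, and how their RNA was prepared, aligned and counted was not given in the sources used here. The genome build, the aligner and the read filters of both kinds of library were likewise not given in the sources used here. No growth label says whether any library came from separate cultures, and with 1 library per group no value has a spread between replicates.

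Each deposited insertion list gives a chromosome, a position and a whole number per line, taken here as the count of reads that support the insertion; the columns have no header. All lists repeat some positions, and such lines were counted as listed, so intervals and tests treat lines at 1 position as separate insertions. For the tests at FLO11 and after stop codons, counting each position once was not tried. The deposited p-value table gives 1 p-value per gene and factor for 6450 genes, computed by the authors with a test, a background and a gene region that the table does not state. The deposited expression table gives RPKM for 6932 features in each RNA library, normalised by the authors to gene length and mapped reads, per the file headers. Low RPKM values were not whole multiples of 1 step, so reads were not recovered and the depth of the RNA libraries is unknown. All value columns of both tables were assigned to a library or a comparison. Gene coordinates are those of the deposited expression table, written here from 1, and its overlapping genes carry merged coordinates, which makes their RPKM uncertain. Gene symbols came from the RefSeq R64 table, which matched 5823 of the 6450 locus tags and left 627 unmatched; none of its coordinates were used.

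To read the deposited p-values as insertion numbers, the 28 values of each gene were fitted from the files. This fit is a description of the table, not the authors' stated method. A Poisson probability of at least the observed number of insertions in the 1200 bp upstream of the start codon was used, with an expected number of 1 plus a background count of the gene scaled by library size to a background of 34110 insertions. The window was chosen by how often it held no insertion exactly where the deposited p-value was at its maximum. Of the windows tried, 1200 bp gave the highest such agreement, a median of 97.1% of genes per factor, and the fit was made at this window only. Within a tolerance of 0.6%, 97.0% of all p-values matched, and 5858 genes (90.9%) matched in all 28 libraries, while 120 genes matched in under 14. Insertion numbers, expected numbers and folds are given only for genes with all 28 values matched. Intervals on insertion numbers are exact Poisson intervals at 95% and cover counting error only, since reads and insertions from 1 pool of colonies are not independent samples of the factor. With no background at a gene, 6 insertions were needed to reach a p-value of 0.001.

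A factor was said to call a gene when the deposited p-value was at or under 0.001. Genes that share an upstream stretch were called together, so factor-locus pairs are given beside factor-gene pairs. Called genes of a factor with overlapping upstream windows made 1 factor-locus pair. Insertions upstream of FLO11 were set against the 27 other libraries pooled with Fisher's exact test, one-sided, with Benjamini-Hochberg adjustment over 28 factors. Called pairs in which the gene encodes 1 of the 28 factors were set against all other genes with Fisher's exact test, one-sided. Shared called genes were measured for each pair of factors by the log2 odds ratio with 0.5 added to each cell, and the median of 16 known partner pairs was compared with that of the other pairs by 100000 permutations of the factor names, two-sided. The added 0.5 raises the log2 odds ratio of factors with few called genes, which bears on this measure. A total of 22 gene lists were tested among the called genes of each factor with Fisher's exact test, one-sided, and adjusted over all 616 tests and over the 13 expected tests alone. All these tests compare libraries, not conditions.

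Expression change was log2((starved + 1)/(rich + 1)) of the RPKM values, a scale that understates the change of low genes, and counts were taken among genes with an RPKM of at least 5 in 1 medium. With 1 library per medium the change has no replicate check and no p-value. A list or a set of called genes was placed by the percentile of its median among 10000 random sets of the same size matched on mean expression, as a description of these libraries. The number of factors that call a gene was related to the absolute log2 change by Spearman's rho across genes with 100000 permutations. Insertions after the stop codon were counted in stretches that lie between the stop codons of 2 convergent genes, up to 1000 bp, and set against the 27 other libraries pooled with Fisher's exact test, one-sided.

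Genes were named by a rule: FLO11, the 28 factor genes, the 15 genes called by the most factors, the 2 genes with the lowest deposited p-value of each factor, the 12 genes with the largest rise and the 12 with the largest fall of RPKM, the 2 members of each list with the largest rise and fall, and the 2 called genes with the largest rise and fall of each factor whose set lay outside 95% of matched sets. Where the text names others, they are members of the lists or were chosen after their values were seen, as were HPF1, STI1, YOR029W, TPS2, KAR4 and FUS1. The groups, tests, lists, partner pairs and naming rule were fixed before the data were examined. The alternatives were stricter p-value thresholds, Benjamini-Hochberg within each factor, insertions against the other libraries, other pseudocounts, no filter, median centring, a shorter stretch after the stop codon and at least 2 reads per insertion. Where insertions were changed, p-values were recomputed from the fit. Other alternatives were added after the data had been seen: each position counted once, libraries thinned to the smallest, shared positions left out, positions with at least 10 times more reads in another library left out, stretches that overlap an upstream window left out, the leading stretch left out, factors with at least 20 called genes, genes with overlapping upstream windows counted as 1 locus (3253 loci), genes that share coordinates left out, and at least 2 reads per insertion for the calls and for FLO11. The filter by reads in another library was devised after shared positions had been noticed, and only the factor 10 was tried. A result for 1 item withheld for evaluation is not reported here. The search for each factor's own DNA motif near its insertions was not run, because no genome sequence was used here.

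Computations were run in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The p-value fit, the calls, the matched random lists and the permutation of factor names were tested on simulated data. The other tests were not. For the p-value fit over 5858 simulated genes, the background was recovered exactly in 100% of genes. For calls in 28 simulated libraries of the real sizes over 5858 genes, 200 of them changed, a median of 35% of 5-fold genes were recovered (6% to 74%), 66% of 10-fold genes (26% to 96%) and 84% of 20-fold genes (54% to 100%). The same simulation gave a median of 3 false calls per library and 62 in the library of the size of Mfg1, since the test does not carry the sampling error of the background. Of 100 random lists among 6444 genes, 7 fell outside the middle 95% of matched lists. Of 40 unrelated sets of calls, 4 gave a permutation p at or under 0.05 for partner pairs.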

Results

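Calling card insertions of 28 transcription factors linked to filamentous growth were mapped in yeast, 1 library per factor, together with the transcriptomes of cells in rich and in nitrogen-starved medium, 1 library each. The 28 libraries held 401017 insertions supported by 62462318 reads. The smallest was that of Rtg1 with 2836 insertions and the largest that of Phd1 with 41619, with a median of 12128.5. In 10 libraries over 15% of the listed insertions repeated a position of the same library. No library had a replicate, so differences between factors carry counting error only.

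The first comparison asked which genes each factor binds. The factors differed widely in the number of genes they called. Mfg1, a partner of Flo8 and Mss11, called 164 genes, Phd1 128, the repressor Nrg1 125, the forkhead factor Fkh1 118 and Sok2 96. In simulated libraries of the same sizes, unchanged genes gave 62 calls for Mfg1, 51 for Phd1, 10 for Fkh1, and 3 each for Nrg1 and Sok2, so part of the calls of the largest libraries is open to chance. Fisher's exact test against the other libraries changed the order, with 203 genes for Phd1, 164 for Hms2 (from 44), 150 for Fkh1, 145 for Mfg1 and 131 for Mga1 (from 36), and adjustment within each factor left 15 for Mga1 and 3 for Rim101. At the other end Smp1 called 4 genes, Rgm1 9 and Rim101 11. Over all factors 1587 factor-gene pairs had a p-value at or under 0.001 in the authors' deposited table. The number of genes times that threshold gives 180.6 pairs. With overlapping windows merged within each factor there were 1084 factor-locus pairs, where a locus counts once for each factor that calls it. The 1587 factor-gene pairs fell on 726 genes, of which 463 were called by 1 factor, 84 by at least 5 and 17 by at least 10. Of these pairs, 119 lay in genes that the RefSeq table did not list.

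**Figure D1:**
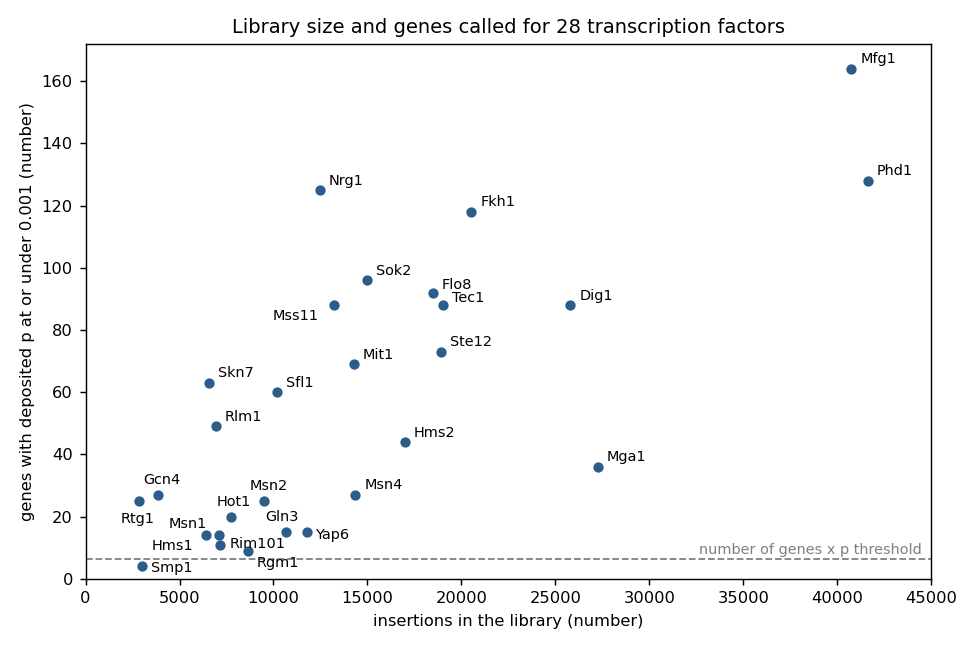
Each point is 1 factor; the x axis gives the insertions in its library and the y axis the genes with a deposited p-value at or under 0.001, and the dashed line marks 6.45, the number of genes times that threshold, which does not allow for library size. Mfg1 with 164 genes and Phd1 with 128 came from the largest libraries, while Nrg1 called 125 genes from 12461 insertions.

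The genes with the strongest calls differed between factors. Rlm1, the factor of the cell wall integrity pathway, placed 535 insertions upstream of the wall protein gene SED1 (exact Poisson interval 491 to 582), 77.6-fold over the expected number, and 518 upstream of GFA1, the first enzyme of chitin precursor synthesis. Hot1, a factor of the response to osmotic stress, called GPD1, a glycerol synthesis gene, at a p-value listed at 0 in the authors' deposited table, and placed 343 insertions upstream of the glycerol transporter gene STL1, 33.3-fold over expectation. Msn1 placed 138 insertions upstream of GLN1, the gene of glutamine synthetase, 27.8-fold over expectation. Skn7 led with CWP2, a wall mannoprotein gene (690 insertions), Nrg1 with its own gene NRG1 (341 insertions, 30.4-fold), Sfl1 with MGA1 (811 insertions, 177-fold) and Sok2 with MMO1 (997 insertions, 185-fold). MMO1 lies next to PHD1 by systematic name, and the same 9 factors called both, so the 2 genes were not told apart as targets. Flo8, Mss11 and Mfg1 shared both leading genes, CIN5 and TUB4, with 1313, 654 and 1734 insertions upstream of CIN5. Ste12, Tec1 and Dig1, the factors of the filamentation and mating kinase pathway, shared PCL2 and TEC1, with 1652, 1535 and 1623 insertions upstream of the cyclin gene PCL2. Smp1 called PIR3 and PIR1, genes of wall proteins, with 29 and 34 insertions.

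Other leading genes were shared by factors of unrelated families. TUP1 and CSM1 led both Fkh1, with 1148 and 1137 insertions, and Gcn4, with 112 and 111. Their expected numbers were equal, 11.8 in Fkh1 and 3.04 in Gcn4, so the counts of both genes may be largely the same insertions. The cell separation gene DSE1 and its divergent neighbour RSP5 led Rtg1, Rgm1 and Yap6, with 48 insertions of Rtg1 and 28 each of Rgm1 and Yap6 upstream of DSE1, and both genes were called by 11 factors. Upstream of the 13 genes called by both Gcn4 and Fkh1, 287 of the 296 Gcn4 positions were also positions of the Fkh1 library, with a median of 1 read per position against 6 elsewhere in the Gcn4 library. Upstream of the 7 genes called by both Gln3 and Dig1, which include TEC1 and STB3, 266 of 278 Gln3 positions were positions of the Dig1 library, with a median of 2 reads against 17 elsewhere.

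Library size went with the number of genes called across the 28 factors (Pearson's r = 0.74, permutation p = 2e-05; Spearman's rho = 0.715, permutation p = 1e-05, the smallest that the permutations can give). Without Mfg1 and Phd1, whose libraries lay farthest from the median size, r was 0.575 (permutation p = 0.0022). No batch was named in the labels, so the relation was not split further.

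The second comparison asked which factors bind FLO11, the gene of the main adhesin of filamentous growth. FLO11 (YIR019C) spans positions 372339 to 375971 of chromosome 9 in the deposited coordinates, and its upstream window spans 375972 to 377171. It was called by 7 factors. Mit1 placed 505 insertions in the window (exact Poisson interval 462 to 551), 90.2-fold over the expected number. These lay at 266 distinct positions. Sfl1, a repressor of flocculation, placed 119 (27.8-fold) and Sok2 56 (9.62-fold). Most Sok2 insertions lay beyond the window, with 52 from 1400 to 1600 bp and 47 from 1600 to 1800 bp upstream against at most 25 in any 200 bp step inside it, and Nrg1 had 7 from 1200 to 1400 bp against 4 in the whole window, so calls from the window alone miss part of the upstream region. Mfg1 followed with 43 insertions (3.04-fold), Tec1 with 22 (3.09-fold), and Flo8 and Ste12 with 20 each (2.87-fold and 2.82-fold). In the authors' deposited table the p-values at FLO11 were 5.55e-16 for Sok2, 5.09e-10 for Mfg1, 5.99e-06 for Tec1, 4.12e-05 for Flo8 and 5.39e-05 for Ste12. Mss11 with 9 insertions and Dig1 with 15 stayed above the threshold, at 0.0871 and 0.0525 in the authors' deposited table. Beyond the window Dig1 had 11 insertions from 1400 to 1600 bp upstream, more than in any 200 bp step inside it. YIR020C, the next gene by systematic name, had p-values of 1.69e-08 for Dig1 and 2.08e-05 for Nrg1 in the authors' deposited table.

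**Figure D2:**
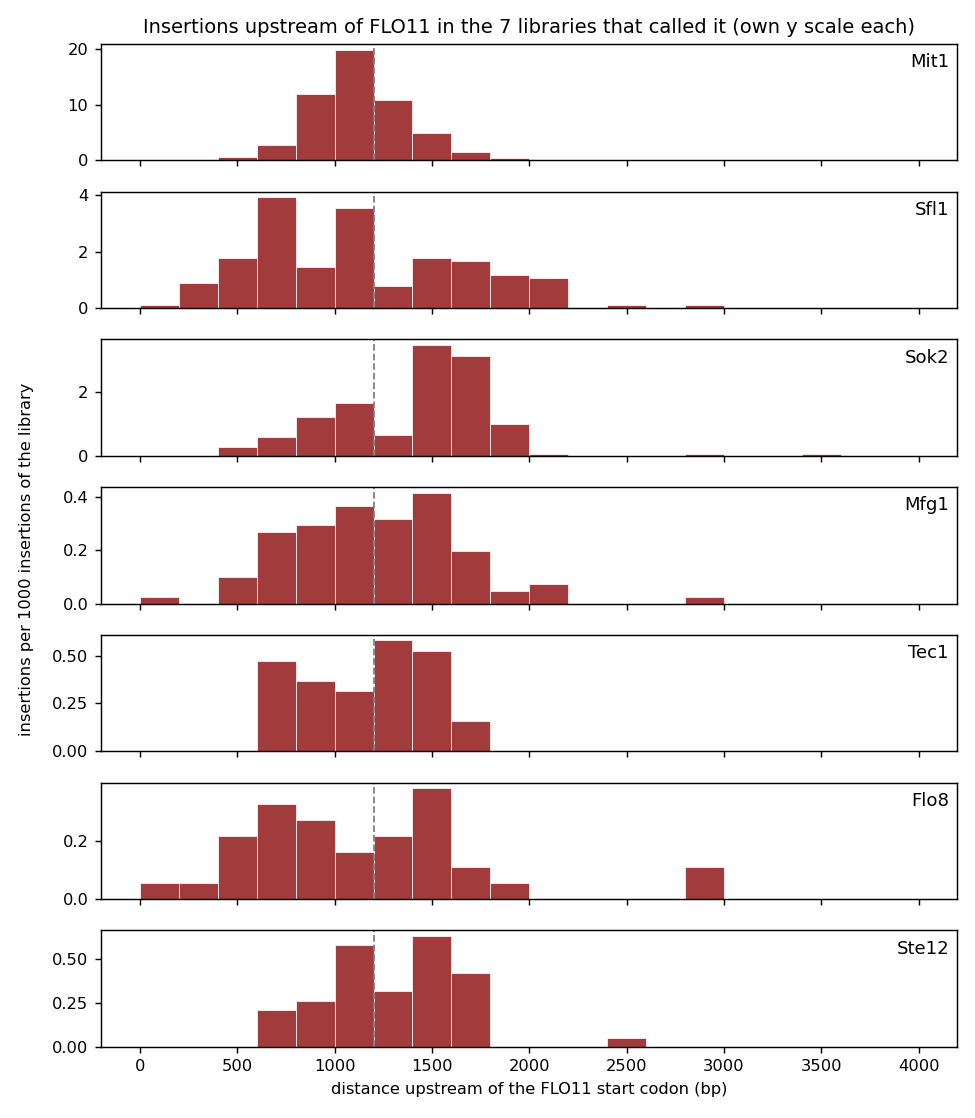
Bars give the insertions of each library per 1000 of its insertions in 200 bp steps upstream of the FLO11 start codon, for the 7 factors that called the gene, each on its own scale from 0; the dashed line marks the end of the 1200 bp window. Mit1 had 505 insertions in the window, the most of the 7.

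Against the 27 other libraries pooled, Mit1 (odds ratio 41.7), Sfl1 (6.35, Fisher's exact test, adjusted p = 7.5e-50) and Sok2 (1.84, Fisher's exact test, adjusted p = 0.00033) were enriched at FLO11. The other factors did not pass, but Mit1 raises the reference of each of them. The 27 libraries other than Mit1 held 0.879 insertions per 1000 there. The remaining factors that called FLO11, Tec1 (1.16), Flo8 (1.08), Ste12 (1.06) and Mfg1 (1.06 per 1000), lay above that rate. Their failure in this test therefore does not speak against binding. All 21 Tec1 positions and all 19 Ste12 positions in the window were also positions of the Mit1 library, as were 15 of 20 for Flo8, 31 of 42 for Mfg1, 39 of 49 for Sok2, 58 of 112 for Sfl1 and 10 of 12 for Dig1. The median read number per position there was 1 for Tec1, Ste12, Flo8 and Mss11, against 7, 7, 8 and 10 in their whole libraries, and 2.5 for Mfg1 against 17, whereas Sok2 had 5 at the window and 5 in its library, Sfl1 26.5 and 46, and Dig1 43 and 28. With insertions of at least 2 reads, 4 factors called FLO11: Mfg1, Sok2, Mit1 and Sfl1. With positions left out where another library had at least 10 times more reads, 3 did, which were Sok2, Mit1 and Sfl1.

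The third comparison asked how the 28 factors bind each other's genes. The factor genes were called far more often than other genes. The gene of Tec1 was called by 13 factors, MGA1 by 11, SOK2, PHD1 and MSN4 by 9 each, HMS1 by 8, and FLO8 and YAP6 by 7 each. Sok2 placed 619 insertions upstream of PHD1 (194-fold) and 235 upstream of FLO8 (27.8-fold), and Dig1 placed 379 upstream of STE12 (68.5-fold). Flo8, Sok2, Ste12, Tec1, Mit1, Nrg1, Phd1 and Rlm1 called their own genes, with 903 insertions of Sok2 upstream of SOK2 and 1175 of Tec1 upstream of TEC1. The genes of Mfg1, Sfl1, Rim101, Rtg1, Skn7, Fkh1, Dig1, Gln3, Msn1, Hot1, Msn2 and Gcn4 were called by no factor.

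Of the 784 possible pairs of a factor and a factor gene, 89 (11.4%) were called, against 0.833% of pairs with other genes (odds ratio 15.2, Fisher's exact p = 3.6e-68). With the 8 calls of a factor on its own gene left out, 81 of 756 remained (odds ratio 14.3, Fisher's exact p = 2.7e-60). With positions left out where another library had at least 10 times more reads, 51 were called (odds ratio 10.4, Fisher's exact p = 9.3e-33). These tests count the pairs as independent, but calls gather on the same genes, such as TEC1, and partner factors call together. The p-values are therefore too small.

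**Figure D3:**
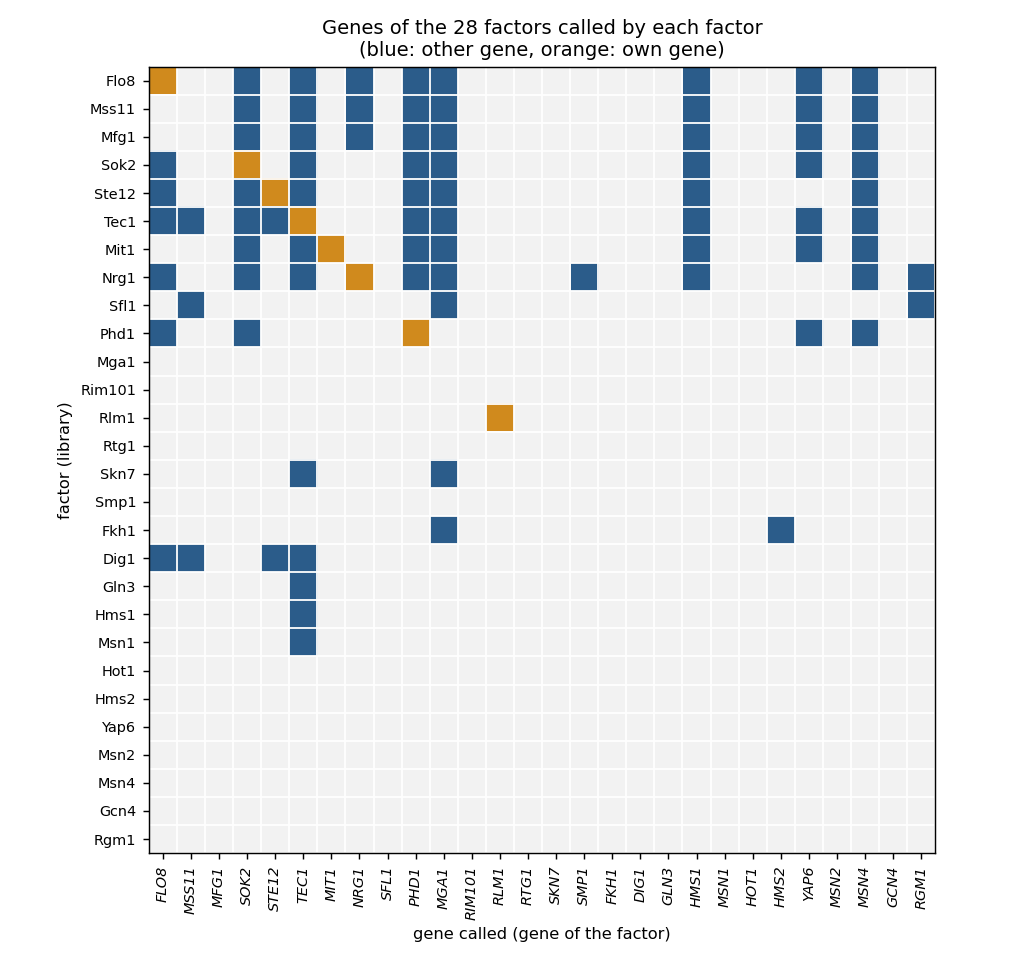
Each line of the grid is a factor and each column the gene of a factor; blue squares mark the 81 calls on the gene of another factor and orange squares the 8 calls on the factor's own gene. The columns of TEC1 and MGA1 hold the most squares, 13 and 11.

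The fourth comparison asked whether 16 pairs of factors fixed beforehand as known partners call the same genes. They held the pairs among Flo8, Mss11 and Mfg1, among Ste12, Tec1 and Dig1, and among Sfl1, Mga1, Skn7 and Hms2. Sok2 with Phd1, Rlm1 with Smp1 and Msn1 with Hot1 were further pairs. Whether the factors of each pair work together was not examined here. The 4 closest pairs were known partners, and 6 of the closest 16 were. Flo8 and Mfg1 shared 91 of the 92 and 164 genes they called, Mss11 and Mfg1 83, Flo8 and Mss11 75, Ste12 and Tec1 67, Tec1 and Dig1 55, and Ste12 and Dig1 47. With positions found in both libraries of a pair left out and p-values recomputed, the shared genes fell from 92 to 35 for Flo8 and Mfg1, from 82 to 21 for Mss11 and Mfg1, from 75 to 51 for Flo8 and Mss11, and from 67 to 39 for Ste12 and Tec1. The log2 odds ratios of these 4 pairs were then 11.9, 8.66, 10.2 and 9.76, so a strong overlap remained. Sfl1 and Mga1 shared 0 called genes, Skn7 and Hms2 0, and Msn1 and Hot1 0. Independent lists would share a mean of 0.488 genes over all pairs, so 0 shared genes says little. The stress factors Msn2 and Msn4 shared 2 of their 25 and 27 genes, with a log2 odds ratio of 4.74 (Fisher's exact test, adjusted p = 0.0099). These 2 were the divergent neighbours DSE1 and RSP5, each called by 11 factors, and the test counts them as separate genes. With positions found in both libraries left out, Msn2 and Msn4 shared 0 genes. The most widely shared genes were TEC1 and PCL2 with 13 factors each and SED1 with 12, followed by CWP2, RPI1 and its neighbour RHO3, SVS1, STB3, MGA1, GFA1, RSP5, DSE1 and SFG1 with 11 each, and CLN1 and GAT2 with 10 each.

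Over the 16 known pairs the median log2 odds ratio of shared genes was 4.88, against 3.88 over the other pairs, a difference that did not pass the test (permutation p = 0.098). Of all 378 pairs, 215 passed Fisher's exact test for shared genes after adjustment, 10 of the 16 known pairs among them. With genes whose upstream windows overlap counted as 1 locus, 182 pairs passed Fisher's exact test, 7 of them known. By locus the log2 odds ratio was 11.3 for Flo8 and Mfg1 and 7.68 for Ste12 and Dig1. It was 0.295 for Sfl1 and Mga1 and 0.223 for Skn7 and Hms2, so the median of known pairs covers unlike pairs. Every p-value rests on the same background. In 100 draws of all libraries and the background from 1 pool of insertions, pairs shared a mean of 0.15 genes and at most 18. The observed values were 7.46 and 91, which argues against sampling error of the background as the source of most of the overlap. The draws cannot show what a background that differs from the libraries would add, and that part was not resolved. The difference between known and other pairs passed the test at a p-value threshold of 0.0001 (2.15, permutation p = 0.014) and with adjustment within each factor (1.99, permutation p = 0.022). It also passed by Spearman correlation of the deposited p-values (0.0474, permutation p = 0.0047) and with positions richer elsewhere left out (1.23, permutation p = 0.026). It did not pass with positions found in both libraries of a pair left out (0.451, permutation p = 0.37), with each position counted once (0.746, permutation p = 0.2), with overlapping windows counted as 1 locus (0.27, permutation p = 0.64) or among factors with at least 20 called genes (1.30, permutation p = 0.054).

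The fifth comparison asked which pathways lie among the called genes. Rlm1 called 8 of the 12 cell wall integrity genes, SED1, CRH1, SLT2, HSP150, CIS3, PIR3, CWP1 and RLM1 (Fisher's exact test, adjusted p = 1.8e-12). Dig1 called 8 of the 18 genes of the filamentation kinase pathway and its targets, Tec1 7 and Ste12 6, which included TEC1, the signalling mucin gene MSB2 and SVS1 (Fisher's exact test, adjusted p = 7e-09, 1.2e-07 and 1.3e-06). Gcn4, the activator of amino acid synthesis, called 7 of 43 genes of that list, among them HIS5, ILV5, HIS3 and ASN1 (Fisher's exact test, adjusted p = 2.6e-08). Msn2 called 6 of 31 general stress genes, TPS1, HXK1, CTT1, GSY2, TSL1 and YGP1 (Fisher's exact test, adjusted p = 8.4e-08), and Rtg1 called the retrograde genes CIT2 and DLD3 (Fisher's exact test, adjusted p = 0.0043).

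Adhesin, cyclin and cell separation genes stood out in other factors. Mit1 called 5 of 7 flocculins and adhesins, FLO1, FLO5, FLO9, FLO10 and FLO11 (Fisher's exact test, adjusted p = 1.3e-07), while Sfl1 and Sok2 called 4 each and Flo8 called FLO1 and FLO11 (Fisher's exact test, adjusted p = 0.049). Mfg1 called 6 of 11 cyclin genes, CLN1, CLN3, PCL1, PCL2, CLB1 and CLB2 (Fisher's exact test, adjusted p = 4.2e-06). Fkh1 called 4 of 8 genes of daughter-cell separation, DSE1, DSE2, SCW11 and CTS1 (Fisher's exact test, adjusted p = 2e-04), and Gcn4 3 of them. Dig1 called the mating genes KAR4, FUS1 and AGA1 (Fisher's exact test, adjusted p = 0.018). Nrg1 called DIT1, DIT2 and IME1 of the meiosis list and Phd1 called NDT80, IME1 and SMK1 (Fisher's exact test, adjusted p = 0.03 and 0.032). The lists passed in 11 factors for the filamentation kinase pathway, 11 for the factor genes themselves, 8 for cyclins, 7 for flocculins and adhesins, 4 for cell wall integrity, 3 for general stress, 2 each for daughter-cell separation and meiosis, and 1 each for mating, the retrograde response and amino acid synthesis. No factor passed for the lists of the cAMP-PKA pathway, nitrogen catabolite repression, autophagy, ribosomal proteins, ribosome biogenesis, glycolysis, the TCA cycle, oxidative phosphorylation, galactose use, hexose transporters or histones.

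In all 51 of 616 tests passed over all tests. The list tests count neighbours called together as separate genes, so their p-values may be too small where list members share an upstream stretch. Of the 13 expected tests, 9 passed adjusted over the list alone and 8 over all tests; the pair that differed was Mfg1 with flocculins (Fisher's exact test, adjusted p = 0.018 over the expected alone and 0.12 over all). Msn4 called 1 stress gene, TPS2, and there were 0 called genes for Gln3 among nitrogen catabolite repressed genes, for Mss11 among flocculins and for Ste12 among mating genes. With positions richer elsewhere left out, Gcn4 called 7 amino acid genes and 0 of daughter-cell separation, Rtg1 called 2 retrograde genes and 0 of cell wall integrity, and Flo8, Mfg1, Ste12 and Tec1 called 0 flocculins. Of the filamentation kinase list Sok2, Mit1 and Gln3 then called 0 genes and Nrg1 1. Dig1, Tec1 and Ste12 kept 8, 7 and 6. Of the cyclins Mit1 and Nrg1 called 0, while Ste12, Tec1 and Dig1 kept 3 each. Rlm1 kept 8 cell wall integrity genes. The meiosis tests of Nrg1 and Phd1 no longer passed (Fisher's exact test, adjusted p = 0.18 and 0.34). The numbers of factors per list thus rest partly on such positions, though the filter also removes true insertions at shared sites.

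The sixth comparison set the transcriptome of nitrogen-starved medium against that of rich medium. Genes of galactose use, nitrogen scavenging and respiration were higher in the starved library, and genes of glycolysis, amino acid synthesis and ribosomes were lower. Among 6006 genes with an RPKM of at least 5 in 1 medium, 183 were at least 4-fold higher and 41 at least 4-fold lower, with a median log2 change of 0.02. All 6 galactose genes were at least 4-fold higher, from 2.48 to 2993 RPKM for GAL7, 9.31 to 5126 for GAL1, 7 to 2882 for GAL10 and 5.22 to 1597 for the transporter gene GAL2, so the cultures differed in the expression of carbon genes as well as of nitrogen genes. Both RNA libraries carry the same label text of growth and 2% galactose induction, which does not give the carbon source of either medium, so the values compare the cultures as a whole and not nitrogen alone.

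Nitrogen catabolite repressed genes, which serve the uptake and use of poor nitrogen sources, had a median log2 change of 2.52, and 28 of 29 were higher, 19 of them at least 4-fold. The proline permease gene PUT4 went from 2.65 to 263 RPKM, the general amino acid permease gene GAP1 from 11.3 to 859.9 and the ammonium permease gene MEP2 from 13.5 to 979. In the TCA cycle and gluconeogenesis list 19 of 20 genes were higher (median 1.99), led by SDH4 (log2 change 3.35) and SDH2 (3.34), and in oxidative phosphorylation 28 of 29 (median 1.76), led by ATP1 (2.16) and QCR6 (2.02). General stress genes had a median of 0.94, with DDR2 from 27.4 to 1168 RPKM, while the chaperone gene HSP30 fell by 1.44 on the log2 scale. These groups moved in the same starved library that held GAL1 at 5126 RPKM. HXK1, from 6.61 to 912 RPKM, shares coordinates with another listed gene, so its value is uncertain. TMA10 (log2 change 6.58) and FDH1 (6.05) were also among the genes with the largest rises, and the RPKM of YLR163W-A and YBR131C-A were listed at 0 in rich medium.

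All 16 genes of glycolysis and fermentation were lower in the starved library (median log2 change -1.08), with ENO2 at -1.92 and ADH1 at -1.78. The low-affinity hexose transporter genes HXT1 and HXT3 had log2 changes of -4.74 and -4.09 while HXT6 had 5.62 and HXT4 1.61, and the 8 transporters together had a median of -0.33, inside the range of matched lists. Ribosomal protein genes had a median of -0.80 with 134 of 138 lower, ribosome biogenesis genes -0.59 with 53 of 53 lower, and amino acid biosynthesis genes -0.67 with 42 of 43 lower, SER3 (-3.29) the most; HIS3 was listed at 0 in both libraries. In the retrograde list IDH1 and IDH2 were higher (2.08 and 1.98) and DLD3 and CIT2 lower (-3.61 and -2.60). Further large falls were those of the aquaporin gene AQY2 (-3.63), MIG2 (-3.28), ARI1 (-3.21) and YDL241W (-3.20). YBR141W-A, YOR161W-A, YKL106C-A and YLL019W-A were listed at 0 in the starved library.

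**Figure D4:**
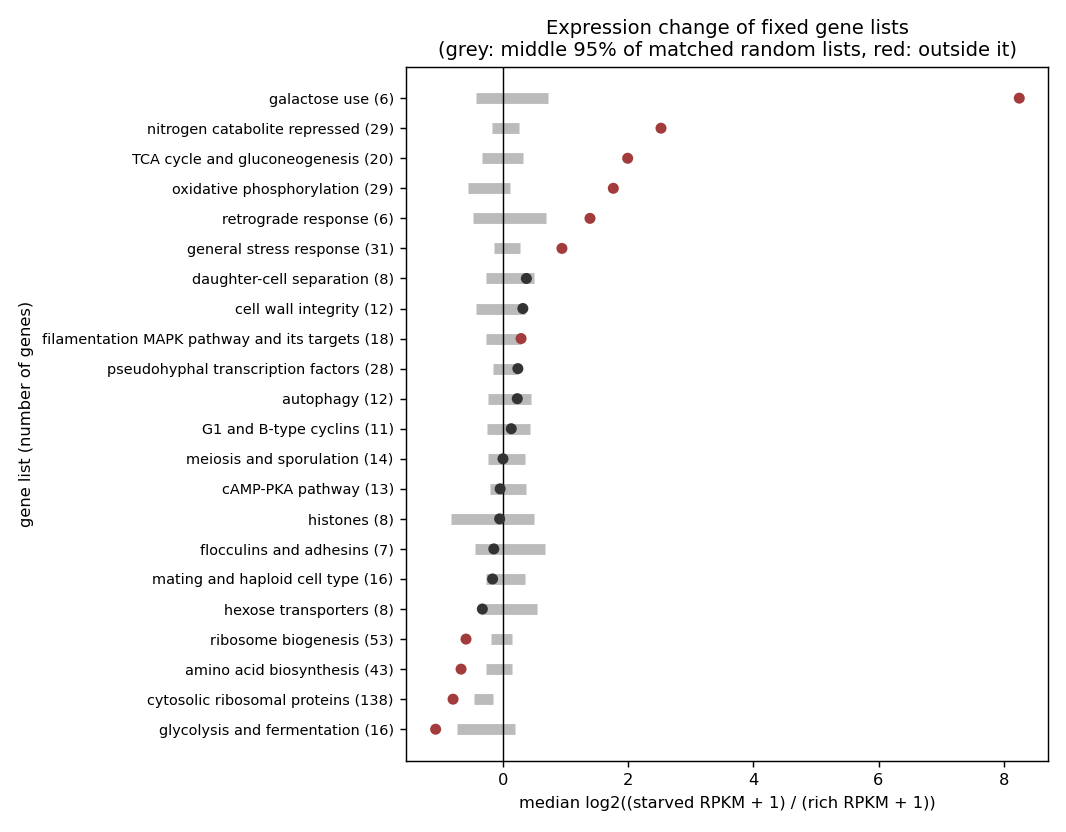
Points give the median log2((starved + 1)/(rich + 1)) of RPKM of each fixed gene list, with its number of genes, and grey bars the middle 95% of 10000 matched random lists; red points lie outside their bar. Galactose use (8.25) and nitrogen catabolite repressed genes (2.52) stand highest and glycolysis and fermentation (-1.08) lowest.

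Among genes of filamentous growth, FLO11 was at 161 RPKM in rich and 54.9 in starved medium, a log2 change of -1.54, and the adhesin gene AGA1 had -1.78. The 7 flocculins and adhesins had a median of -0.15, inside the range of matched lists. The filamentation kinase list had a median of 0.29, just outside it, led by the pectinase gene PGU1 (2.71) and SVS1 (2.37). Of the factor genes MSN4 (2.37), NRG1 (2.29), PHD1 (1.28), HMS1 (1.26), TEC1 (1.17) and SMP1 (1.02) were more than 2-fold higher and MGA1 (-1.76) was lower, and the list as a whole had a median of 0.24, inside the range. The lists of the cAMP-PKA pathway (-0.05), mating (-0.17), autophagy (0.23), meiosis and sporulation (0.00), cyclins (0.13), histones (-0.05), daughter-cell separation (0.37) and cell wall integrity (0.32) also lay inside the ranges of matched lists. Outside theirs lay galactose use, nitrogen catabolite repressed genes, TCA cycle, oxidative phosphorylation, retrograde response, general stress and the kinase list above, and amino acid biosynthesis, ribosomal proteins, ribosome biogenesis and glycolysis below.

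The seventh comparison asked how the expression of called genes differed between the media. Genes called by 12 factors had a higher median log2 change than matched sets after adjustment over 28 factors, and those of Sfl1 a lower one. The median was 0.36 for the 92 genes of Flo8 and for the 88 of Mss11, 0.38 for Ste12, 0.36 for Tec1, 0.29 for Mfg1, 0.26 for Sok2, 0.22 for Mit1, 0.46 for Skn7 and 0.93 for the 14 genes of Msn1. Fkh1 (0.13), Hot1 (0.45) and Msn4 (0.33) were the others, and Sfl1 had -0.15. PUT4 (6.17) and the transporter gene HXT6 (5.62) were the highest among the genes of Flo8 and Mfg1, SPS4 (3.10) and NCA3 (3.05) among those of Mss11, PRY2 (3.02) and NFG1 (2.82) among those of Ste12, and STL1 (3.20) among those of Hot1. MGA1, with -1.76, was among the 2 lowest genes of Flo8, Mss11, Sok2, Ste12, Tec1, Mit1, Skn7 and Fkh1. The share of matched sets as extreme was 0.0002, the smallest that 10000 sets can give, for Flo8, Mss11, Mfg1, Ste12, Tec1, Skn7 and Msn1. The set of Dig1 lay outside 95% of matched sets but not after adjustment. The sets overlap, since Flo8, Mss11 and Mfg1 share most of their genes. Neighbours called together count as separate genes, as in the 92 genes of Flo8 at 56 loci, while matched sets draw single genes. The shares may therefore be too small. The galactose list, which differed most between the libraries, held 0 called genes.

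Genes called by more factors had larger absolute changes across genes. The median absolute log2 change was 0.32 for the 5719 genes called by 0 factors, 0.37 for those called by 1, 0.55 for those called by 2 to 4 and 0.64 for those called by at least 5, and the share changed at least 2-fold went from 12.3% for 0 factors and 18.4% for 1 to 35.7% for at least 5. Spearman's rho was 0.0877 over 6444 genes (permutation p = 1e-05, the smallest that the permutations can give). Genes are not independent replicates, and the relation describes these 2 libraries.

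The eighth comparison asked whether insertions also gather beyond the end of called genes, since the series concerns chromosome dynamics. Flo8, Mss11 and Mfg1 placed many insertions between the stop codons of CIN5, a leucine zipper factor gene, and STI1, at positions 381464 to 382170 of chromosome 15. There Flo8 had 703 insertions, or 38.0 per 1000 of its library against 4.63 per 1000 in the other libraries (odds ratio 8.49), Mfg1 963 (odds ratio 5.74) and Mss11 403 (odds ratio 5.84; Fisher's exact test, adjusted p = 1.8e-152). The insertions of Flo8, Mfg1 and Mss11 lay at 339, 403 and 230 distinct positions, and the tests count repeated positions as separate insertions. The CIN5 coding region itself, at 382171 to 383058, held 47, 46 and 9 insertions. Mit1 placed 925 insertions in the stretch after the stop codon of MGA1, where Sfl1 placed 182, and Flo8 placed 243 after that of HPF1.

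Over all such stretches of their called genes, 9 of 28 factors had more insertions than the other libraries, with odds ratios of 4.19 for Flo8, 2.91 for Mss11, 4.31 for Mfg1, 8.13 for Mit1, 4.14 for Sfl1, 2.73 for Rlm1, 1.99 for Hms2, 1.76 for Dig1 and 1.30 for Sok2 (Fisher's exact test, adjusted p = 2.7e-04 for Sok2). Without its leading stretch Mss11 had an odds ratio of 0.667 and Sfl1 0.641, and 4 factors passed with odds ratios of 2.18 for Flo8, 3.61 for Mfg1, 2.30 for Mit1, which had 925 of its 1240 insertions at MGA1, and 1.25 for Sok2. With positions richer elsewhere left out Sok2 turned to an odds ratio of 0.683 and Hms2 (1.51) did not pass either. Fkh1 went from 0.92 to 3.90 and passed, and Mit1 had 24.9. The rate of Fkh1 itself fell from 5.51 to 3.68 per 1000, and that of the other libraries fell more, from 5.99 to 0.946. Its stretches changed with its calls, from 58 to 42. An odds ratio below 1 can likewise come from the reference. For Mss11 the stretch at MGA1 alone gave the other libraries 4.18 per 1000. The CIN5 stretch overlaps the 1200 bp window upstream of YOR029W by 135 bp, outside of which lay 535 of the 703 Flo8, 330 of the 403 Mss11 and 775 of the 963 Mfg1 insertions; with every stretch that overlaps such a window left out, 6 of the 9 factors passed, Flo8 with an odds ratio of 2.14, Mfg1 3.20, Sok2 1.73, Mit1 15.7, Sfl1 4.35 and Dig1 5.30, while Mss11 (0.424), Rlm1 (2.02) and Hms2 (1.82) did not.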

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

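The values below lie outside the comparisons above and were looked at after the data had been seen. All 28 libraries held insertions at position 3642 of chromosome 3, near the left end of the chromosome and outside every upstream window. Together they had 815944 reads there, 1.31% of all reads. The position held the most reads of any in 17 libraries and from 0.0943% of the reads of Fkh1 to 4.96% of those of Gcn4.

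Outside every 1200 bp upstream window lay 72643 insertions, or 18.1% of the total, with 39526 of them in gene bodies and 33117 between genes. Their share ranged from 6.53% to 43.9% between libraries.

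The expression table holds 488 features that have no p-value in the binding table, and 116 of them had an RPKM of at least 5 in 1 medium. Of these 4 were at least 4-fold higher in the starved library and 17 at least 4-fold lower. The 4 were tRNA features listed at 0 in rich medium. The 17 had SNR or tRNA names, and some were listed at 0 in the starved library. Genes with flocculin names among the 116, picked after their values were seen, changed less. They were FLO16, with 4.5 RPKM in rich and 7.17 in starved medium, and LgFLO1, with 4.63 and 10.6.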

How the results depend on the processing

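In this part the settings that processing lists as added were chosen after the data had been seen. Of 53 alternatives over 11 results, 43 kept the direction and the side of the threshold, or a count within 1.5 times, and 0 reversed, where the result after the stop codon was judged by its number of factors. Called pairs numbered 592 instead of 1587 with every library thinned to the size of the smallest, since fewer insertions enter. FLO11 was called by 3 factors instead of 7 by Fisher's exact test against the other libraries, a test in which Mit1 raises the reference, by 3 with positions richer elsewhere left out and by 4 with at least 2 reads. Calls on factor genes numbered 51 instead of 89 with positions richer elsewhere left out. That filter also removes true insertions at sites that partners share, so its drop does not measure insertions from other libraries. Insertions after the stop codon passed in 4 factors instead of 9 without the leading stretch, where the cause was not tested. Single odds ratios turned below 1 there, to 0.667 for Mss11 and 0.641 for Sfl1, and to 0.683 for Sok2 with positions richer elsewhere left out. The difference between known and other pairs moved past its threshold, to 2.15 at a p-value threshold of 0.0001, 1.99 with adjustment within each factor, 0.0474 by Spearman correlation and 1.23 with positions richer elsewhere left out; the cause was not tested. With overlapping windows counted as 1 locus it was 0.272, and its permutation p ranged from 0.0047 to 0.64 over its alternatives. Leaving out genes called by more than 14 factors removed 0 genes. The motif search and its distances were not run, and no replicate could be left out with 1 library per group. Library size limits the calls: among simulated 10-fold genes, 26% were recovered at the size of Rtg1 and 96% at that of Mfg1. No paired analysis was possible because each group has 1 library.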

Other observations

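In this part the tests at FLO11 and the test of Skn7 and Fkh1 together against Rtg1 were chosen after the result was seen, and the 3 pairs of libraries compared first were picked after insertion rates and shared positions of some pairs had been seen. At FLO11 only 3 of the libraries with at least 5 positions were tested. The mating genes below were picked after their values were seen. Genes that mark the mating type differed widely in both RNA libraries. The α-factor genes were at 4804 RPKM for MF(ALPHA)1 and 831 for MF(ALPHA)2 in rich medium, and at 2423 and 217 in starved medium. The receptor gene STE3 was at 106 and 113 RPKM. In contrast STE2 was at 2.47 and 3.46 and the protease gene BAR1 at 2.84 and 2.97, and the a-factor gene MFA1 at 42.9 and 45.1. MFA2 was at 17.2 RPKM in rich medium and higher in starved medium by 1.51 on the log2 scale, opposite to the α-factor genes. No label gives the mating type or ploidy of the cultures.

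The number of called genes differed between the 28 factors, and library size went with it. With every library thinned to 2836 insertions in 20 draws, the numbers still varied by more than counting noise, with a variance-to-mean ratio of 16.7 where depth alone would have left it under 2. Mfg1 called 61.0 genes on average after thinning and Hms2 0.1, while Phd1 went from 133 recomputed calls to 4.2 and Mga1 from 41 to 0.2. This argues against depth as the whole cause of the differences, though the calls of the largest libraries depended on it. What the factors themselves contribute stays open and was not tested.

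Known partners shared more called genes than other pairs, with a median log2 odds ratio of 4.88 against 3.88, a difference that did not pass its test and may be chance. From recomputed p-values the difference was 0.87 (permutation p = 0.15). With positions found in both libraries of a pair left out it was 0.451 (permutation p = 0.37), with each position counted once 0.746 (permutation p = 0.2), and from the deposited p-values with overlapping windows counted as 1 locus 0.272 (permutation p = 0.64). Insertions at identical positions and repeated positions cannot be told apart from shared binding as its source, since 51.5% and 85.3% of the recomputed difference remained. The recomputed difference had not passed the test before either change, so its failure after them decides nothing.

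Some leading genes recurred in libraries of unrelated factors, and a candidate explanation is that reads of 1 library were counted in another. Of the Gcn4 positions upstream of genes shared with Fkh1, 97.0% were Fkh1 positions, against 21.2% elsewhere. Of the Gln3 positions upstream of genes shared with Dig1, 95.7% were Dig1 positions, against 10.0% elsewhere. Both shares were over the 90% set before these were run, and both came with low read numbers. In those windows Fkh1 held 12.7% and Dig1 32.2% of the bases. At FLO11, where Mit1 held 22.2% of the window's bases, 100% of Tec1 and 100% of Ste12 positions were Mit1 positions, and 75% of Flo8 positions, which stays open. Dig1 (83.3%) and Sok2 (79.6%) also shared Mit1 positions there, with a median of 43 and 5 reads against 28 and 5 in their libraries, so position alone does not settle the source. For Rtg1 55.3% of positions upstream of genes shared with Skn7 were Skn7 positions, against 1.97% elsewhere and with a median of 1 read against 17, which argues against Skn7 as the whole source but not as part of it, and 71.7% were positions of Skn7 or Fkh1, which leaves both together open, while shared hot spots and biological explanations were not tested.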
